A study of Mus musculus with 3 samples.

How the data were processed

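The data were total RNA sequencing libraries of the chromatin fraction of mouse bone marrow-derived macrophages, made after ribosomal RNA depletion, with 1 group and 3 libraries. Each library had a gene table, a transcript table of the same layout and a second transcript table of another layout. Per the file headers and the notes deposited with each library, the values refer to genome mm10 and annotation M21. The column names match the output of RSEM for the gene table and the first transcript table, and of kallisto for the second transcript table, and the layouts are named after these programs here. The programs, their versions and the aligner are not given in the sources used here. The authors' gene and transcript tables hold expected counts, which are estimates and need not be whole. The authors' TPM values, per the file headers, are scaled for effective transcript length within each library. The authors' deposited FPKM values in the gene and first transcript tables are scaled for length and library size. The second table gives estimated counts and TPM, per the file headers.

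The gene tables had 81881 entries, of which 55536 were genes, and all of these matched GENCODE M21 by identifier, which gave symbols, biotypes and mm10 coordinates. Of the rest, 26248 entries carried only a number, 96 were ERCC spike-in sequences and 1 was the phiX sequence. These entries stayed out of the library sizes used for CPM and out of comparisons. They took 2.46, 0.484 and 0.327% of counts in replicates 1, 2 and 3, almost all on phiX. The deposited TPM values of the gene table were not rescaled without them, and phiX held 5631, 874 and 739 TPM there. The second table lacked 86 of the genes, which entered its comparisons at 0. Total expected counts per library were 13953780, 24222661 and 16571228, phiX included. A gene at 0 counts could have up to 3 counts at this depth, which is 0.220, 0.125 and 0.182 CPM for replicates 1, 2 and 3. Floors and the Wilson intervals of shares cover counting error only, and reads are not independent molecules. Bootstrap intervals were drawn over genes and show the spread between genes, not between libraries.

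Replicates were taken from the labels, which call them biological replicates but give all of them the same donor entry, so their spread may in part be technical. With 1 group, no comparison between groups was possible and no test between groups was run. Before the data were examined, 31 gene lists, 6 pairs of lists, all settings and the alternatives were fixed. For each list, log2(TPM + 1) was averaged over libraries, and the list median was set against 10000 random lists of the same size from all protein-coding, long noncoding or small noncoding genes. Lists outside the central 95% were called high or low. Pairs of lists were treated in the same way. A gene could belong to more than 1 list, and members of both lists of a pair stayed in both. Where a symbol occurred more than once the gene with the lowest identifier of the list's class was used. Snhg16 had no match. The list of sex chromosome genes was used only to describe the libraries.

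Variation between replicates was the SD of log2 CPM (counts scaled to library size) over the 3 libraries, from expected counts rounded to whole numbers, with TMM factors of edgeR 4.0.16 (1.03, 0.984 and 0.985) and a prior count of 2. Genes with a mean of at least 50 counts entered, in lists with at least 5 such genes, and random lists were matched on mean expression in 20 bins. Dispersion was estimated in edgeR with an intercept only. Size factors of DESeq2 1.42.0 were an alternative. Retained-intron shares used transcripts of that biotype, 21848 in the annotation, in genes of at least 1 TPM, with random lists matched on transcript number and TPM. Analyses ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots in matplotlib.

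The gene naming rule was fixed in advance. It took the 3 highest members and the lowest member of each list by mean TPM, the 15 highest protein-coding genes outside the mitochondrial genome and the 10 highest noncoding genes, the 10 most variable protein-coding genes at a mean of at least 10 TPM, and a fixed set of inflammatory, macrophage and reference genes. Genes named outside this rule are said to be so. Methods were tested on simulated data. With a true coefficient of variation of 0.25 over 24865 genes the estimate was 0.262, and shifts of 1 and 2 log2 units in 200 genes came back as 0.94 and 2.08. Of random lists of 20 unshifted genes 5.6% were called, and of lists raised by 2 log2 units 42.0%, so a list that was not called may still differ. For variation, 40 lists of 20 genes shifted 2 or 4 fold in 1 simulated library were called in 100% of draws, and 40 unshifted lists in 2.5%. Smaller shifts were not simulated for this measure. Removal of a GC and length trend, used for 1 test in the closing section, returned 0.998 for a deviation of 1 over 200 genes. Its bins were made finer, 40 by GC and 5 by length, after the first simulation left part of the trend in place, and with these bins a trend of 0.708 fell to 0.022. The value of that test had been seen once with the coarser bins, and its outcome did not change.

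Alternatives were other pseudocounts, FPKM, CPM without length correction, the second quantification, a minimum mean TPM, TPM over nuclear protein-coding genes, length-matched random lists, other count minimums, other scalings and leaving out each replicate in turn. For reads from overlapping or antisense genes, paralogs and pseudogenes, the tables do not show how they were divided, so values of such genes are uncertain.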

Results

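Total RNA was sequenced from the chromatin fraction of mouse bone marrow-derived macrophages, primary cells of strain C57BL/6J, after depletion of ribosomal RNA. Chromatin-associated RNA is enriched in transcripts that are still being made or processed. The cells had been exposed to Lipid A, the part of bacterial lipopolysaccharide that activates the receptor TLR4, at 100 ng/ml for 12 h, left without it for 12 h, and exposed again at 100 ng/ml for 20 min. The series held 1 group of 3 libraries, labelled biological replicates 1, 2 and 3. Cells without the first or the second exposure were not analysed here, so every level below describes macrophages after the second exposure and no value is an effect of the treatment. The libraries held 13953780, 24222661 and 16571228 expected counts for replicates 1, 2 and 3. The labels give 1 µg, 250 ng and 500 ng of starting RNA for the same replicates, so starting amount and replicate cannot be told apart. Genes with a TPM (transcript level scaled for length and library size) of at least 1 numbered 14597 ± 369 (SD, n = 3), and 13400 passed this level in all 3 libraries. Gene levels below are mean TPM ± SD over the 3 libraries (n = 3). Gene lists were fixed before the data were examined, and a list was called high or low when its median lay outside the central 95% of 10000 random lists of the same size. Genes are not replicates, so these percentiles describe these libraries and no p-value is given.

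The first question was which gene programmes were represented in chromatin RNA 20 min into the second exposure. Interferon-stimulated genes stood highest of the fixed lists. All 36 members reached 1 TPM in every library, and the list median lay 6.36 log2 units above that of all protein-coding genes (per-library mean 6.36 ± 0.49, n = 3). Mx1, encoded on chromosome 16 (97447035 to 97462907, mm10), was the most abundant protein-coding gene outside the mitochondrial genome, at 1961 ± 757 TPM. Parp14 had 728 ± 198 TPM and Stat2, a transcription factor of interferon signalling, 615 ± 155 TPM. Irf1 had 258 ± 106 TPM and Ifit1 79.2 ± 39.4 TPM. The lowest member, Isg20, had 14.8 ± 12.0 TPM. The percentile of the list among random lists was 100.

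Genes of macrophage identity formed the next highest list, 5.52 log2 units above background (per-library mean 5.56 ± 0.27), with all 34 members at 1 TPM or more in every library. The cathepsin Ctsb had 434 ± 102 TPM, the surface receptor Adgre1 (F4/80) 334 ± 54.4 TPM and the inhibitory Fc receptor Fcgr2b 279 ± 85.9 TPM. Lysozyme Lyz2 had 185 ± 53.5 TPM, the growth factor receptor Csf1r 141 ± 34.2 TPM and the lineage transcription factor Spi1 53.8 ± 19.2 TPM. The lowest member, Cebpa, had 2.38 ± 0.87 TPM. Genes of alternative activation were not called, with a median 0.34 log2 units below background (difference -0.34). Of 11 such genes, 4 reached 1 TPM in every library, led by Il4ra at 63.0 ± 7.76 TPM, Mrc1 at 42.5 ± 13.7 TPM and Clec10a at 6.54 ± 2.85 TPM, while Mgl2 was listed at 0. The identity list lay 5.86 log2 units above the alternative activation list (per-library mean 5.75 ± 0.35), a pair difference at the 100 percentile of random pairs.

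Primary response genes of the TLR4 pathway, which need no newly made protein for induction, were abundant on chromatin. Their median lay 4.93 log2 units above background (per-library mean 5.10 ± 0.67) and 13 of 14 members reached 1 TPM in every library. Nfkbia, which encodes the NF-kB inhibitor IkBa, had 164 ± 81.8 TPM. Tnf, encoded on chromosome 17 (35199381 to 35202007, mm10), had 159 ± 134 TPM, and Zfp36, a protein that promotes decay of cytokine mRNA, 154 ± 78.6 TPM. The phosphatase gene Dusp1 had 90.9 ± 48.0 TPM, Cxcl2 55.7 ± 41.1 TPM and Il1b 44.4 ± 20.1 TPM. The lowest member was the prostaglandin synthase gene Ptgs2 at 5.41 ± 3.30 TPM.

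Secondary response genes, most of which need newly made proteins or chromatin remodelling for induction, were not called high, with a median 0.20 log2 units above background and a percentile of 53.8, and below background in the second quantification (-0.37). Of 12 members, 5 reached 1 TPM in every library. Il6 had 0.75 ± 0.72 TPM, Il12b 0.15 ± 0.10 TPM, Nos2, the inducible nitric oxide synthase, 3.77 ± 3.35 TPM and Lcn2 1.28 ± 0.86 TPM, and Il12a was listed at 0. The most abundant members were the interferon-inducible Mx1 and Ifit1 and the acute phase gene Saa3 (116 ± 73.5 TPM). The primary list exceeded the secondary list by 4.74 log2 units, a 26.6-fold difference in median TPM + 1, in all 3 libraries (per-library mean 4.88 ± 0.58). Among genes with a mean of at least 1 TPM the difference was 0.43 and was no longer called, since that filter removes the secondary genes near 0.

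Inflammatory cytokine genes were called high, 1.92 log2 units above background (per-library mean 2.33 ± 0.70), but their members were split. Of 34 genes, 18 reached 1 TPM in every library. Ccl5 had 198 ± 171 TPM, Cxcl10 169 ± 172 TPM and Ccl4 81.8 ± 61.1 TPM, while Csf2, the gene of the growth factor GM-CSF, was listed at 0 in all 3 libraries. The call was lost without replicate 1 (1.77, percentile 97.2) and in CPM, which is not scaled for length (1.93, percentile 95.4). Negative regulators of TLR4 signalling were called high at 3.73 log2 units above background (per-library mean 3.78 ± 0.29), with 27 of 31 members at 1 TPM or more in every library. Acod1, which makes itaconate, had 261 ± 225 TPM, Trim30a 230 ± 48.6 TPM, Tnip3 225 ± 149 TPM and Tnfaip3, which encodes the deubiquitinase A20, 119 ± 65.3 TPM. Socs3 had 30.2 ± 21 TPM, the kinase-like inhibitor Irak3 20.9 ± 5.0 TPM and Il10 11.8 ± 5.49 TPM, and the lowest member, Sigirr, had 0.42 ± 0.14 TPM. The regulators exceeded the cytokines in all 3 libraries, by 1.81 log2 units, but this difference lay at percentile 94.9 of random pairs and was not called, and among genes with a mean of at least 1 TPM it was -0.15.

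Components of the TLR4 pathway were called high at 3.87 log2 units above background (per-library mean 4.03 ± 0.29). The kinase Ikbke had 1041 ± 180 TPM, Tbk1 151 ± 12.3 TPM and Map3k8 114 ± 35.5 TPM, and Lbp, a serum protein gene, had 0.95 ± 0.16 TPM. The 5 NF-kB subunit genes lay 3.6 log2 units above background at percentile 96.4 and were not called. Nfkb1 had 79.6 ± 14.9 TPM, Nfkb2 29.5 ± 8.37 TPM, Relb 19.6 ± 5.72 TPM and Rela 14.6 ± 5.03 TPM. The list was called high in CPM (5.37) and in the second quantification (3.74), where Rela had 43.9 ± 10.2 TPM and Relb 29.8 ± 9.39 TPM, the reverse order. Immediate early genes, which respond within minutes, were called high at 2.06 log2 units (percentile 98.2; per-library mean 2.13 ± 0.62). Mcl1 had 284 ± 98.2 TPM, Klf6 123 ± 60.1 TPM, Junb 99.9 ± 41.3 TPM, Fos 67.8 ± 38.1 TPM, Atf3 32.3 ± 14.3 TPM and Egr1 27.8 ± 10 TPM, and Fosl1 had 0.15 ± 0.14 TPM. This call was lost in the second quantification (1.55), without replicate 3 (1.87) and against length-matched random lists, and among genes with a mean of at least 1 TPM the list lay at -0.07. The immediate early list lay below the TLR4 pathway list in all 3 libraries (difference -1.81), which was not called, but was called low among genes with a mean of at least 1 TPM (-1.37). Antimicrobial effector genes were not called (0.45 above background), with Sod2 at 280 ± 140 TPM, the receptor gene Clec4e at 91.6 ± 69.4 TPM and Slpi listed at 0.

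**Figure D1:**
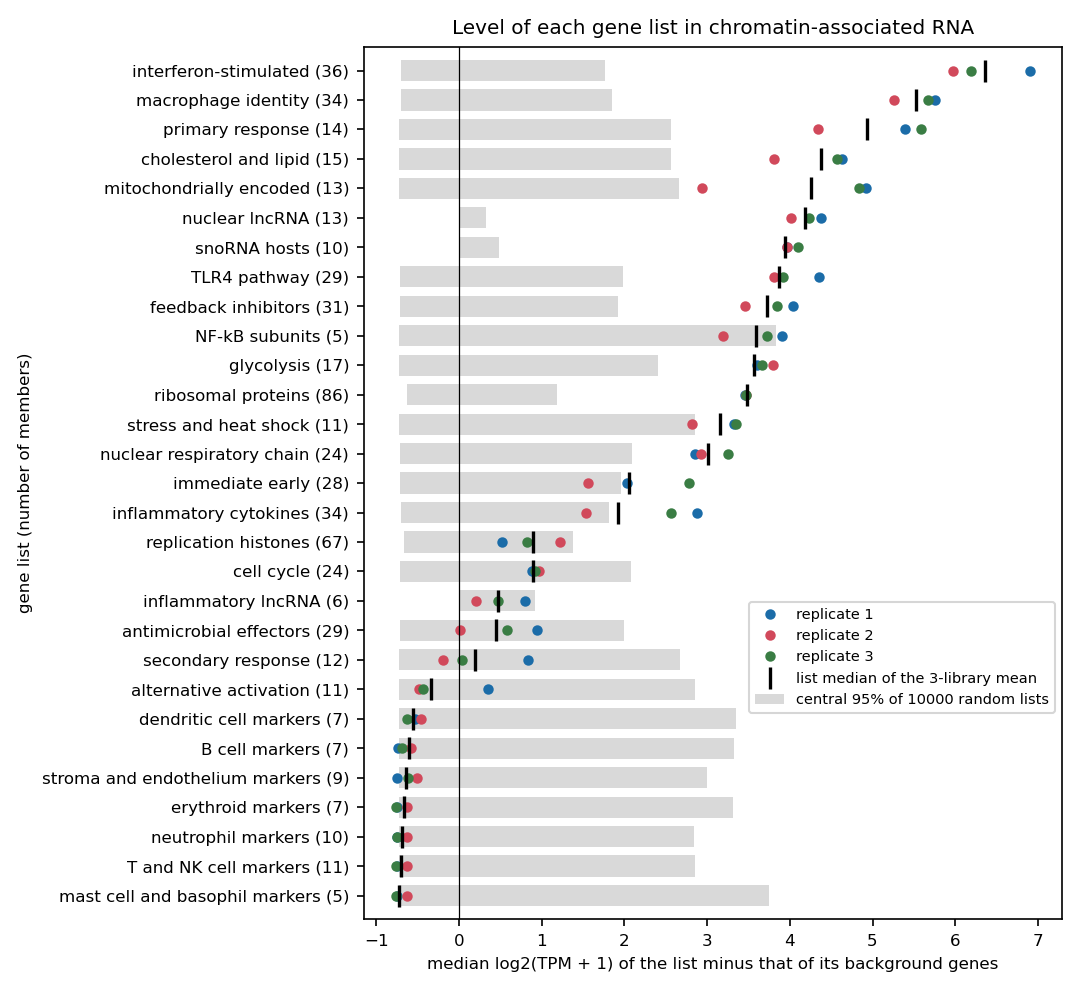
Level of 29 gene lists, as the median log2(TPM + 1) of the members minus the median of the background genes, with 1 point per replicate library, a tick for the median of the 3-library mean, and grey bars for the central 95% of 10000 random lists. Interferon-stimulated genes lie 6.36 log2 units above background, while secondary response genes lie at 0.20, inside the grey bar.

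**Figure D2:**
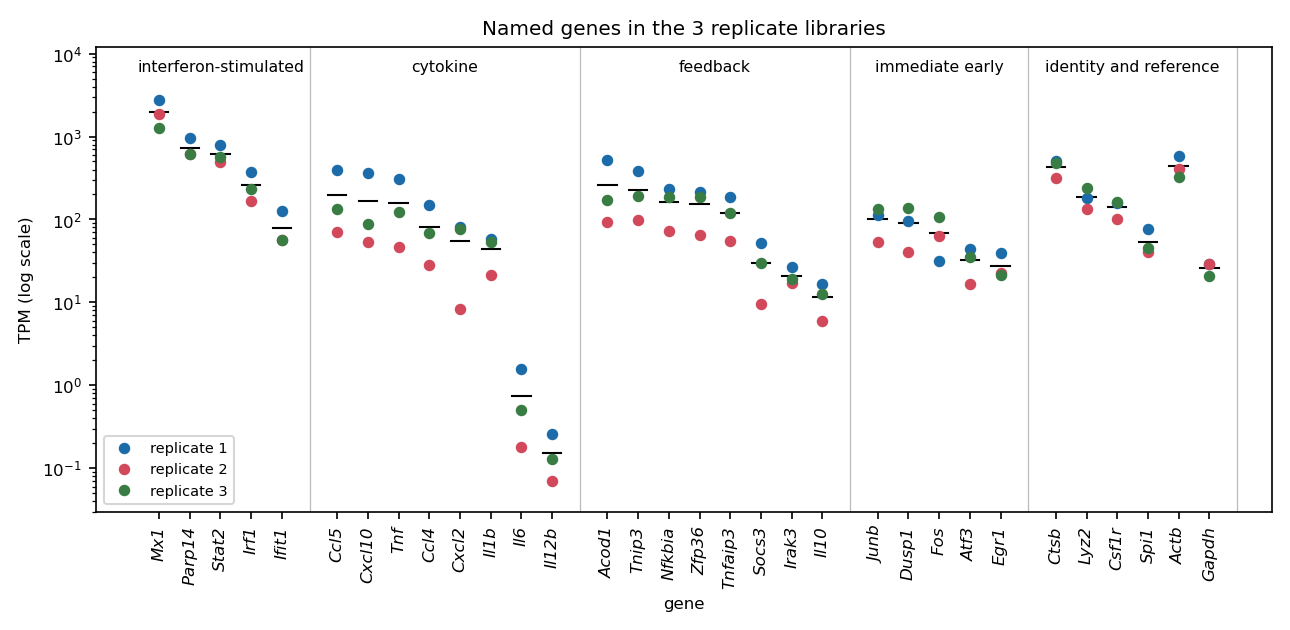
TPM on a log scale of named genes in the 3 replicate libraries, 1 point per library, with a line at the mean. Tnf spans 46.8 to 307 TPM between libraries and Il6, at a far lower level, 0.18 to 1.56 TPM. Their SDs of log2 CPM are alike, at 1.18 and 1.23.

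Genes of basic metabolism and of lipid handling were also high in chromatin RNA. The cholesterol and lipid list lay 4.38 log2 units above background, with the lipid exporters Abca1 at 114 ± 15 TPM and Abcg1 at 81.2 ± 8.37 TPM, the nuclear receptor Nr1h3 at 63.3 ± 22.2 TPM and the desaturase Scd1 at 0.08 ± 0.05 TPM. Glycolysis genes lay 3.56 above background (Hk3 at 310 ± 50.5, Pkm at 107 ± 3.75, Pfkfb3 at 75.9 ± 11.5 and Slc2a1 at 1.32 ± 0.28 TPM). Ribosomal protein genes lay 3.48 above (Rpl10 at 127 ± 2.24, Rps9 at 121 ± 14.4 and Rpl3 at 92.0 ± 6.26 TPM), and the nuclear genes of the respiratory chain 3.01 above (Atp5b at 76.3 ± 6.13, Sdha at 73.7 ± 23.6 and Ndufs1 at 40.1 ± 3.27 TPM). These 2 lists differed by 0.47 log2 units, which was not called, but was called high against length-matched lists and turned to -0.08 in CPM. Stress and heat shock genes lay 3.15 above (Hspa8 at 96.8 ± 27.6, Gadd45b at 81.5 ± 48.4 and Ddit3 at 67.3 ± 29.4 TPM). Mitochondrially encoded genes lay 4.25 above, led by mt-Atp8 at 267 ± 170 TPM and mt-Co1 at 225 ± 121 TPM. Their order depended on the measure. In replicates 1, 2 and 3 mt-Atp8 had 114, 40 and 116 counts, against 5216, 3209 and 4582 for mt-Co1. In the second quantification mt-Atp8 had 87.5 and mt-Co1 161 TPM. The mitochondrially encoded mt-Co2 was listed at 0 in all 3 libraries and had 4.98 ± 8.50 TPM in the second quantification, a mean smaller than its SD. Cell cycle genes (0.89 above; Pcna at 22.0 ± 3.17, Mki67 at 7.49 ± 1.34 and Mcm6 at 7.23 ± 1.11 TPM) and replication histone genes (0.89 above; Hist3h2a at 38.5 ± 7.0, Hist2h2aa2 at 30.8 ± 10 and Hist2h2ac at 20.1 ± 2.79 TPM) were not called. Both were called low, at -1.39 and -1.51, among genes with a mean of at least 1 TPM, where glycolysis (0.74) and respiratory chain genes (0.25) were no longer called high. Replication histones were called high against length-matched lists. In CPM the mitochondrial (2.84) and respiratory chain (2.33) lists were not called.

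Markers of other cell types that a bone marrow culture can hold lay below the background median and none of their lists was called. The differences were -0.70 for T and NK cells, -0.61 for B cells, -0.69 for neutrophils, -0.56 for dendritic cells, -0.64 for stroma and endothelium, -0.66 for erythroid cells and -0.72 for mast cells and basophils. The most abundant member in each was Cd4 (8.32 ± 2.71 TPM), Ms4a1 (0.12 ± 0.09), Csf3r (89.8 ± 29.7), Zbtb46 (1.41 ± 0.19), Kdr (4.92 ± 4.61), Alas2 (11.0 ± 2.79) and Ms4a2 (0.10 ± 0.12). Apart from Csf3r, a receptor that macrophages also express, neutrophil genes were below 1 TPM, with Ngp at 0.81 ± 0.40 TPM and Cxcr2 listed at 0, although the second quantification gave Cxcr2 4.42 ± 1.61 TPM. In this quantification random lists of these sizes also reach a median of 0, so a list of absent genes cannot be called low, while in the second quantification the erythroid and the mast cell and basophil lists were called low (both -1.73).

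Nuclear long noncoding RNAs were 4.18 log2 units above all long noncoding RNA genes (per-library mean 4.21 ± 0.18), and small nucleolar RNA host genes 3.94 above (4.01 ± 0.07). Malat1, a nuclear speckle RNA encoded on chromosome 19 (5795690 to 5802672, mm10), had 28664 ± 6390 TPM, the paraspeckle RNA Neat1 2060 ± 180 TPM and Xist, the RNA that coats the inactive X chromosome, 1090 ± 155 TPM. Among host genes, Gas5 had 181 ± 14.6 TPM, Zfas1 99.9 ± 18.5 TPM and Snhg1 40.5 ± 5.24 TPM, and Snhg3, the lowest, 5.40 ± 0.99 TPM. The difference between these lists was 0.24 log2 units and was not called, but it was called high in CPM (2.12), among genes with a mean of at least 1 TPM (1.32) and without replicate 2 (0.38), and was 0.05 without replicate 1. Long noncoding RNAs linked to inflammation were not called (0.48 above), with Mir22hg at 80 ± 17.6 TPM and Mir155hg, the host of microRNA 155, at 35.3 ± 34.8 TPM. For small structured RNAs the list median and the background median were both 0, so this comparison says nothing. Of 176 members, 119 were listed at 0 TPM in every library, which for such short RNAs need not mean 0 counts. The list was called high in the second quantification (4.58) and among genes with a mean of at least 1 TPM (4.88).

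The next question was which gene groups differed most between the replicate libraries. Inflammatory genes varied far more than other genes of like expression. Over 22 cytokine genes with a mean of at least 50 counts, the median SD of log2 CPM was 0.96, against 0.19 for matched random lists, and 20 were highest in replicate 1 while 19 were lowest in replicate 2. Tnf had 307, 46.8 and 122 TPM in replicates 1, 2 and 3, Cxcl10 367, 52.9 and 87.9, and Cxcl2 82.0, 8.29 and 76.7. On the TPM scale the median protein-coding gene was also 0.29 log2 units higher in replicate 1 than in replicate 2. In log2 CPM by TMM, the highest library exceeded the lowest 5.10 fold for Tnf, 6.63 fold for Cxcl10 and 6.50 fold for Cxcl2. The other lists with high variation were mitochondrially encoded genes (median SD 1.08), antimicrobial effectors (0.87), primary response genes (0.72), negative regulators (0.64), secondary response genes (0.56), immediate early genes (0.49), interferon-stimulated genes (0.42), cell cycle genes (0.34) and macrophage identity genes (0.29). These calls are not independent, because lists share members. All secondary response genes and nearly all primary response genes also belong to the cytokine, regulator, immediate early, antimicrobial or interferon-stimulated lists. All 36 interferon-stimulated genes were highest in replicate 1, and 28 were lowest in replicate 3, while on log2(TPM + 1) 35 were highest in replicate 1 and 26 lowest in replicate 2. On that scale 4907 of 9540 protein-coding genes were highest in replicate 1 and 6749 lowest in replicate 2. The count of interferon-stimulated genes lowest in replicate 2 is thus near the share of all genes. Of 29 negative regulators, 23 were highest in replicate 1 and 22 lowest in replicate 2, with Acod1 at 517, 94.1 and 173 TPM. Of 20 immediate early genes, 11 were highest in replicate 1 and 9 in replicate 3. Fos, encoded on chromosome 12 (85473890 to 85477273, mm10), went against the cytokines, with 31.7, 64.0 and 108 TPM.

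The 10 protein-coding genes with the largest SD at a mean of at least 10 TPM were Cxcl2 (SD 1.56 log2 units), Cxcl10 (1.43), Rgs1 (1.36), Cd69 (1.32), Ccl3 (1.32), Ccl12 (1.31), Fabp4 (1.24), Clec4e (1.23), mt-Atp8 (1.22) and Tnf (1.18). Rgs1, a regulator of chemokine receptor signalling, had 179, 26.7 and 106 TPM and the activation marker Cd69 41.6, 5.15 and 18.2 TPM. By contrast, TLR4 pathway genes (median SD 0.14), nuclear respiratory chain genes (0.16), ribosomal protein genes (0.22), stress genes (0.21), NF-kB subunits (0.22), cholesterol and lipid genes (0.23), glycolysis genes (0.26), host genes of small nucleolar RNAs (0.31), replication histones (0.35) and small structured RNAs (0.80) were not called. Of these, only the TLR4 pathway list was uncalled under every alternative. Replication histones were called high at a mean count of at least 10 (0.58), with length matched as well, without replicate 1 (0.33) and without replicate 3 (0.43), and host genes and ribosomal protein genes were called low on log2(TPM + 1) (0.12 and 0.19) but high without replicate 1 (0.37 and 0.20). Nuclear long noncoding RNAs varied less than matched genes, at 0.10, a call that was lost without replicate 1 or replicate 2, at a mean count of at least 500 and on log2(TPM + 1). The interferon call rested on replicate 1 and the mitochondrial call on replicate 2, since the median SD was 0.14 and 0.13 without them, inside the random ranges. Without replicate 2 the medians of primary response genes (0.37), negative regulators (0.37), antimicrobial effectors (0.55) and immediate early genes (0.32) were lower but still called, and that of NF-kB subunits was 0.04. Secondary response genes were not called without replicate 1 (0.24), nor cell cycle genes without replicate 2 (0.20) or replicate 3 (0.34), at a mean count of at least 10 (0.35) or on log2(TPM + 1) (0.21).

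**Figure D3:**
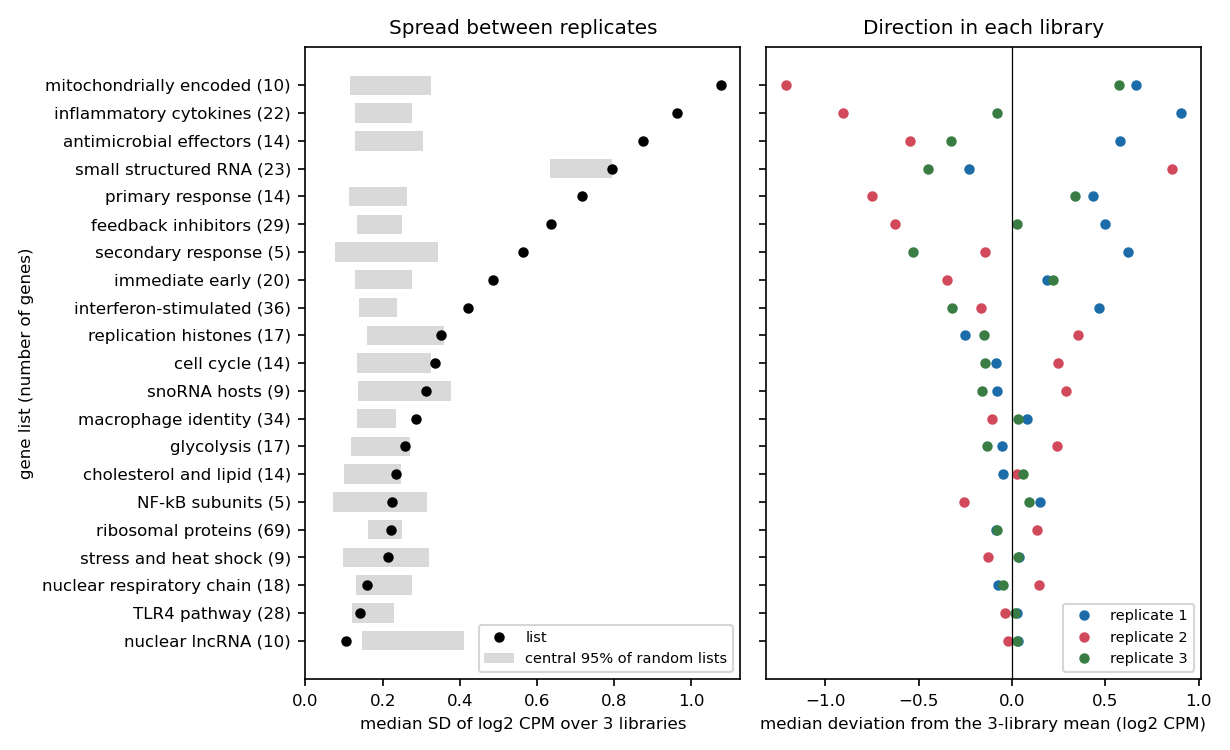
Left, median SD of log2 CPM over the 3 libraries for each gene list (points), with the central 95% of expression-matched random lists in grey. Right, the median deviation of each list from the 3-library mean in each replicate, which was 0.91 in replicate 1 and -0.91 in replicate 2 for cytokine genes.

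RNA classes were compared by their share of each library. Protein-coding genes took 65.1 ± 3.68% of expected counts (n = 3), long noncoding RNAs 30.3 ± 3.79% and small noncoding RNAs 1.14 ± 0.10%. Classes were those of the annotation, and few genes made up the share annotated as long noncoding. Gm26917, encoded on chromosome 17 (39843013 to 39846341, mm10), took 13.5 ± 3.19% and Malat1 10.6 ± 0.50%, followed by Gm42418 (1.53 ± 0.53%), Xist (1.33 ± 0.10%) and Neat1 (1.14 ± 0.10%). The largest protein-coding share belonged to Rnf213, an interferon-inducible ubiquitin ligase, at 1.22 ± 0.33%, and 10 genes together took 30.8 ± 4.37% of counts. Gm26917 and Gm42418 together took 10.9, 16.0 and 18.2% of counts in replicates 1, 2 and 3. Whether these reads came from long noncoding RNA was not examined, so the long noncoding share is uncertain. Without Gm26917 and Gm42418, a choice made after the data were seen, the long noncoding share was 18.0%. Genes annotated as ribosomal RNA took 0.60 ± 0.44% of counts.

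On the TPM scale the order of the classes was different. Small noncoding RNAs took 55.9 ± 4.70% of TPM, protein-coding genes 29.4 ± 4.74% and long noncoding RNAs 11.2 ± 1.90%. The most abundant noncoding genes in TPM were the small nucleolar RNA Gm22988 (80411 ± 15894 TPM), Gm26447 (59212 ± 34054), the ribonuclease RNA Rmrp (56844 ± 19204), Gm26917 (47000 ± 12355), Snord15b (33440 ± 4044), Malat1, Snord22 (18599 ± 17404), Gm25835 (17336 ± 13666), Rn7sk (14386 ± 7743) and Gm22513 (14144 ± 5830). TPM divides by an effective length that is close to 0 for RNAs shorter than the sequenced fragments, and Snord22 had 2251 counts but 0 TPM in replicate 2. In the second quantification Gm22988 had 7395 TPM. After Mx1, the most abundant protein-coding genes were Lilrb4a (1401 ± 730 TPM), Rsrp1 (1308 ± 242), H2-K1 (1232 ± 421), Tcirg1 (1160 ± 45.7), Fyb (1085 ± 246), Ikbke, Zeb2 (1039 ± 292), Hnrnpa2b1 (992 ± 30.3), Gpnmb (951 ± 428), Rnf213 (934 ± 97.4), Fth1 (887 ± 296), Lilr4b (887 ± 487), Rbm39 (853 ± 96.6) and Samhd1 (819 ± 190). Actb had 437 ± 134 TPM and Gapdh 26.3 ± 4.94 TPM.

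**Figure D4:**
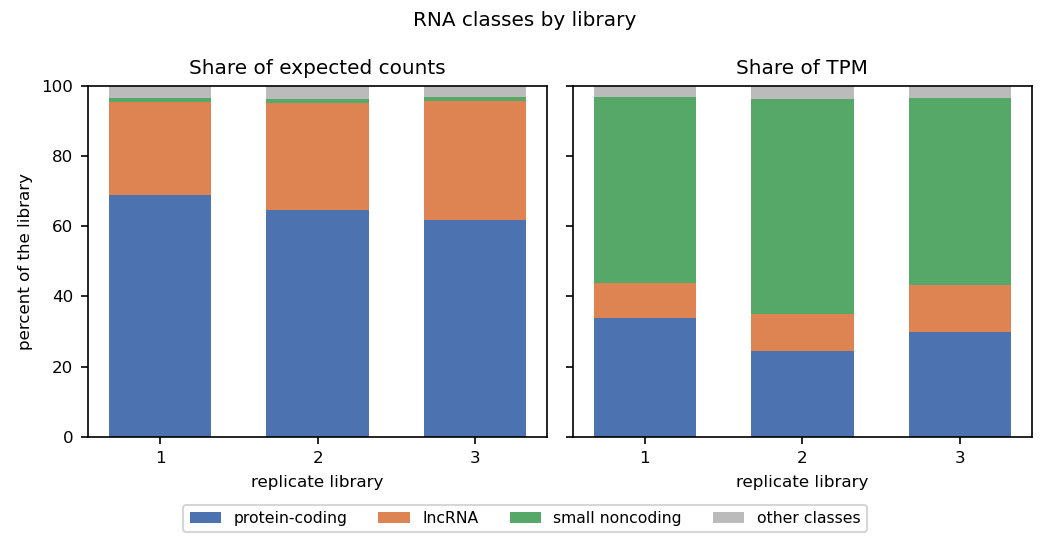
Share of each RNA class in percent of expected counts (left) and of TPM (right), 1 stacked bar per replicate library. Protein-coding genes hold 65.1% of counts and 29.4% of TPM on average, while small noncoding RNAs hold 1.14% and 55.9%.

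Transcripts annotated as retaining an intron were examined next, since chromatin RNA includes partly spliced molecules. Among 6330 genes with such a transcript and at least 1 TPM, the median share of the gene's TPM on retained-intron transcripts was 47.1 ± 0.95% (n = 3). Ribosomal protein genes had a higher share than matched genes, 61.5% over 66 genes, with Rpl3 at 93.7 ± 1.41% and Rpl10 at 85.1 ± 1.69%. Nuclear respiratory chain genes had 62.0% over 16 genes and primary response genes 68.7% over 6 genes, ranging from Nfkbia at 7.86 ± 1.61% to Dusp1 at 96.3 ± 0.59%. The medians of the other lists were 64.4% for cytokines, 67.0% for antimicrobial effectors, 54.8% for stress genes, 53.8% for cell cycle, 53.4% for glycolysis, 53.0% for the TLR4 pathway, 49.4% for interferon-stimulated genes, 47.6% for cholesterol and lipid genes, 40.6% for negative regulators and 39.8% for macrophage identity, and none was called, although antimicrobial effectors were without replicate 2 (71.2%). The respiratory chain call was lost without replicate 1 (59.6%) or replicate 3 (61.1%). All 3 calls were lost in the second quantification, where the shares were 53.1% for ribosomal protein genes, 51.3% for respiratory chain genes and 55.3% for primary response genes. Reads in introns outside annotated transcripts are not counted in either table.

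The replicate libraries resembled one another closely over all genes, although they differed by more than sampling noise. Across genes, Pearson r of log2(TPM + 1) was 0.976 for replicates 1 and 2, 0.981 for 1 and 3 and 0.979 for 2 and 3, and 0.988 to 0.991 for protein-coding genes. Genes are not independent replicates, so r describes the libraries and carries no p-value. The chi-square per degree of freedom between the counts of each pair was 58.9, 40.7 and 29.1 for the same pairs, so no library was a copy of another. The common biological coefficient of variation was 0.213, and without replicate 3 it was 0.25. The quantifications of the same libraries by both programs ranked genes less alike than the replicates did, with Spearman rho between 0.759 and 0.767 over all genes and between 0.867 and 0.881 over genes with a mean of at least 1 TPM. Of 119 named genes with a mean of at least 1 TPM, 23 were higher by more than 1.5 times in the second quantification, among them Spi1 (130 TPM), Ccl4 (170 TPM), Hk3 (572 TPM) and Nfkbia (304 TPM), and 10 were lower, among them Rmrp, Snord15b and mt-Atp8 (87.5 TPM).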

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

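Signal outside the analysed genes was found in each library above the 3 counts that a count of 0 allows. The phiX sequence, a bacteriophage genome often added as a sequencing control, had 343001 counts in replicate 1, 117292 in replicate 2 and 54142 in replicate 3, which were 2.46% (95% Wilson interval 2.45 to 2.47), 0.484% (0.482 to 0.487) and 0.327% (0.324 to 0.330) of counts. Entries that carried only a number had 33, 52 and 21 counts. No explanation was tested for these counts. In the weighing below, the tests of ribosomal protein genes and of the starting amount were chosen after the result was seen.

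Cytokine genes were 1.89 log2 units higher in replicate 1 than in replicate 2 (bootstrap 95% interval over 22 genes 1.22 to 2.43). With all libraries thinned to the smallest total the median SD was 0.98, above the random range of 0.13 to 0.28. Thinning can only add counting noise to values already scaled to library size, so this test cannot decide on library depth. In libraries simulated with counting noise only, the median SD over 9542 genes was 0.056. Counting noise of that size does not reach the spread of the cytokine genes. It was not simulated for the cytokine genes alone, and counting noise is larger for genes with few counts. At a mean count of at least 500 the median SD of the cytokine genes was 0.85 and was still called high. Carry-over of cytoplasmic mRNA would raise ribosomal protein genes as well, but these were lower in replicate 1, with a difference of -0.20 (interval -0.30 to -0.11), and on the TPM scale their difference of 0.14 was still below that of the median protein-coding gene, 0.29. Mitochondrially encoded genes, whose RNA also lies outside the nucleus, were 1.78 log2 units higher in replicate 1. Ribosomal protein genes had a median 61.5% of their TPM on transcripts annotated as retaining an intron, so their values reflect mature mRNA only in part. No rise of ribosomal protein genes was thus seen, but carry-over of cytoplasmic mRNA or of other cytoplasmic material is not decided. The starting amount of RNA cannot be told apart from a difference between the cultures, because there is 1 library per amount; that 18 of the 22 genes followed the order of the stated amounts adds nothing, since the pattern itself largely fixes this count, and no biological explanation of this pattern was tested.

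Mitochondrially encoded genes were low in replicate 2, by a median difference of -1.82 log2 units from the mean of the other libraries over 10 genes. Division of reads between mitochondrial genes and nuclear copies by 1 program is argued against, since the second quantification gave -1.93, below the random range of -0.42 to -0.03. A lower carry-over of cytoplasmic mRNA would lower ribosomal protein genes too, but these were higher in replicate 2 by 0.20 (interval 0.13 to 0.30). On the TPM scale their difference was -0.14, against -0.27 for the median protein-coding gene, so this comparison rests on values relative to all genes. It also rests on genes whose values reflect mature mRNA only in part, so it does not decide on carry-over of cytoplasmic mRNA. Carry-over of mitochondria themselves and the starting amount stay open and were not tested.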

How the results depend on the processing

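List levels, pair differences, list variation, class shares, retained-intron shares, detection, agreement measures and the TPM of some named genes were recomputed. Each was recomputed under those alternatives, fixed before the data were examined, that applied to it. Count shares and SDs of single genes were not recomputed. The removal of Gm26917 and Gm42418 was chosen only after the class shares were seen. No paired analysis was possible because there is 1 group. Of 287 alternatives for list levels, 268 left the call as it was, and of 161 for variation between replicates 136 did.

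Levels, in log2 units above background. Immediate early genes were not called in the second quantification (1.55), among genes with a mean of at least 1 TPM (-0.0711), against length-matched lists (2.06) or without replicate 3, with 1.87 to 2.19 over single replicates left out. Cytokine genes were not called in CPM (1.93) or without replicate 1, with 1.77 to 2.65 over single replicates left out. NF-kB subunits became high in CPM (5.37) and in the second quantification (3.74). Small structured RNAs became high in the second quantification (4.58) and at a mean of at least 1 TPM (4.88). At that minimum replication histones (-1.51) and cell cycle genes (-1.39) became low, and respiratory chain (0.25) and glycolysis genes (0.74) were not called. Replication histones became high against length-matched lists (0.89). In CPM mitochondrially encoded genes (2.84) and respiratory chain genes (2.33) were not called. Erythroid (-1.73) and mast cell markers (-1.73) became low in the second quantification. Levels that were not called also changed sign: antimicrobial effectors at a mean of at least 1 TPM (-0.77), alternative activation genes in the second quantification (0.10), secondary response genes there (-0.37) and without replicate 1 (-0.08), and replication histones in CPM (-0.08) and in the second quantification (-0.15).

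Pair differences. Primary minus secondary response genes were not called at a mean of at least 1 TPM (0.43). Nuclear long noncoding RNAs minus host genes became high in CPM (2.12), at 1 TPM (1.32) and without replicate 2, with 0.0530 to 0.380 over single replicates left out. Ribosomal protein minus respiratory chain genes became high against length-matched lists (0.47), and changed sign in CPM (-0.08). Immediate early minus TLR4 pathway genes became low at 1 TPM (-1.37). Negative regulators minus cytokines changed sign at 1 TPM (-0.15).

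Variation, as median SD in log2 units. On log2(TPM + 1), which also carries the shift of all genes between libraries, NF-kB subunits (0.44) and stress genes (0.39) became high, host genes (0.12), ribosomal protein genes (0.19) and respiratory chain genes (0.12) low, and nuclear long noncoding RNAs (0.25) and cell cycle genes (0.21) were not called. Nuclear long noncoding RNAs were also not called at a mean count of at least 500 (0.0992). With single replicates left out they had 0.0856 to 0.104, and were not called without replicate 1 or 2 (0.0930). Interferon-stimulated (0.135 to 0.570 over single replicates left out) and secondary response genes (0.235 to 0.778) were not called without replicate 1, and mitochondrially encoded genes (0.131 to 1.31) not without replicate 2. Without replicate 1 host genes (0.373), small structured RNAs (1.11, range 0.226 to 1.11), ribosomal protein genes (0.197, range 0.111 to 0.228), glycolysis genes (0.262, highest 0.271) and lipid genes (0.234, lowest 0.128) became high. Without replicate 2 primary response genes had 0.368, negative regulators 0.368, antimicrobial effectors 0.553 and immediate early genes 0.318, all still called, while NF-kB subunits had 0.0435, host genes 0.117 and respiratory chain genes 0.0767, not called. Secondary response genes had 1.06 at a mean count of at least 10, and TLR4 pathway genes 0.254 on log2(TPM + 1), not called. Replication histones became high at a mean count of at least 10 (0.578), matched on length as well (0.351), and without replicate 1 (0.333) or replicate 3, with 0.224 to 0.434 over single replicates left out. Cell cycle genes were not called at a mean count of at least 10 (0.349), without replicate 2 (0.196) or without replicate 3 (0.337), and had 0.359 without replicate 1.

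Other results. In the second quantification 22665 genes reached 1 TPM. The mean correlation between replicates was 0.935 at a mean of at least 1 TPM, 0.973 with a pseudocount of 0.1 and 0.976 to 0.981 with single replicates left out, lowest without replicate 3, where the coefficient of variation was 0.25. Agreement of the quantifications was 0.874 at 1 TPM or more and 0.824 without genes shorter than 200 bases. The protein-coding share was 29.4% of TPM, 91.6% of counts without the 10 largest genes and 76.6% without Gm26917 and Gm42418. For long noncoding RNAs these were 11.2, 3.16 and 18.0%, and small noncoding RNAs had 55.9% of TPM and 1.34% of counts without Gm26917 and Gm42418. Retained-intron shares in the second quantification were 55.3% for primary response, 53.1% for ribosomal protein and 51.3% for respiratory chain genes, none called. Respiratory chain genes had 59.6% without replicate 1 and 61.1% without replicate 3, not called, and 61.8% without replicate 2, and antimicrobial genes became high without replicate 2 (71.2%, against 65.9% without replicate 3). In the second quantification Nfkbia had 304 TPM, Neat1 1585 TPM and Irak3 26.6 TPM.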

Other observations

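In the weighing of the interferon-stimulated genes, the test of the starting amount was chosen after the result was seen. The sex chromosome genes matched female libraries in every replicate. Xist had 1123, 921 and 1226 TPM, while the Y-linked genes Ddx3y and Eif2s3y had 0 counts in all 3 libraries, and Kdm5d and Uty had at most 1 count in a library. Tsix, which overlaps Xist on the other strand, had 0.09 ± 0.04 TPM (n = 3). In the second quantification Uty had 13.0 TPM and Ddx3y 1.5 TPM, so low values of single genes depended on the program.

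Genes chosen after their values were seen showed that some rapid-response genes differed between libraries in another way than the cytokines. Fosb had 0.15, 0.50 and 5.56 TPM in replicates 1, 2 and 3, Nr4a1 1.07, 1.87 and 9.08 TPM, and Fosl2 1.84, 1.76 and 10.6 TPM, each highest in replicate 3 together with Fos. Cd14, the co-receptor that hands lipopolysaccharide to TLR4, had 37.8, 22.8 and 116 TPM. Relative to all protein-coding genes, small nucleolar RNA host genes were higher in replicate 2 than in the mean of the others, by 0.41 log2 units by TMM and 0.33 on the TPM scale (9 genes). Between replicates 1 and 2, TPM scaling moved the median protein-coding gene by 0.29 log2 units, against -0.04 by TMM. Among the mitochondrial genes, mt-Atp6 had 29.4 TPM in replicate 1 and was listed at 0 in the other libraries, while the second quantification gave it 51.6 ± 32.7 TPM.

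Interferon-stimulated genes were highest in replicate 1, with a median deviation of 0.47 log2 units from the 3-library mean. A trend with GC content and gene length is argued against as the whole cause, since after its removal the deviation was 0.47 (random range -0.03 to 0.13) and 36 of 36 genes were still highest in replicate 1. The hypothesis that 1 difference in activation, shared with fast-response genes, set replicate 1 apart was tested on genes outside the fixed lists, chosen after the fixed lists had been seen but before their own values were: replicate 1 exceeded replicate 3 by 0.59 (interval 0.49 to 0.67) in 49 interferon-stimulated genes but by -0.10 (-0.41 to 0.15) in 31 fast-response genes. Between replicates 1 and 3, the only pair tested, this argues against a difference shared with fast-response genes as a set. The fixed cytokine genes were also higher in replicate 1 than in replicate 3, by 0.91 (0.33 to 1.35), so a difference shared with cytokine genes stays open. Against replicate 2, replicate 1 was higher by TMM in the fixed immediate early (0.53) and primary response genes (1.21) as well as in the fixed interferon-stimulated genes (0.63). A difference between replicates 1 and 2 shared with fast-response genes thus stays open. A steady effect of the starting RNA amount, which needs lower values in replicate 2 than in replicate 3, was not decided either, since relative to all protein-coding genes replicate 2 exceeded replicate 3 by 0.10 (0.06 to 0.26) by TMM and by 0.06 (-0.02 to 0.24) on the TPM scale, both inside the random ranges.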
